A study of Mus musculus with 6 samples.

How the data were processed

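The samples were 6 RNA-seq libraries of splenic CD4+ T cells of C57BL/6 mice, 3 cultured for 48 h with 5 mM itaconate and 3 with 5 mM NaCl, all in the presence of antibodies against CD3 and CD28 and 200 U of IL-2. Per the labels' protocols, RNA was isolated with an RNeasy kit, had an integrity number above 7, and was made into libraries and sequenced by a service provider. Each library was assigned to its group by its title, and the columns of the table by their treatment code and replicate number, with the code NAC read as the NaCl control arm. NaCl is the only other treatment in the labels, but the code is not explained in the sources used here and could also stand for N-acetylcysteine, so the identity of the control values rests on this reading.

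The authors deposited a single table of normalized estimated counts per gene symbol, an expression signal that is never negative. Per the submitters' processing notes, the mm10 genome, STAR 2.7.0f and RSEM 1.3.0 were used. The gene annotation, the tool that made the size factors, the strand setting and any filter are not given in the sources used here. In every library 100% of values were multiples of a hundredth of a fixed step (within 0.01 hundredths), as RSEM counts with 2 decimals divided by a size factor would be, and the step gave the size factor and the estimated total. Between 79.9% and 82.2% of values were whole reads within 0.02 reads, so whole reads were not recovered, and count models were not used. The median ratio to the geometric mean library was 1.01 in each of the 6 libraries, as median-ratio scaling gives. Normalized estimated counts are relative to the other genes of a library, so a change shared by most genes would not be seen, and a gene's reads can be divided by RSEM with near-identical copies.

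The table held 55401 entries with 55291 distinct symbols. For the 107 symbols on several entries the entry with the highest mean kept the symbol. All 6 values were 0 for 34124 entries. Genes with a mean of at least 10 over the 6 libraries were tested (13180), of which 98.3% had a symbol in GENCODE release 21 of GRCm38, used here for positions, lengths and GC content. Values were taken as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, with an intensity trend of the variance and no covariate, two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05. A fold change is on the log2(value + 1) scale and understates the change of genes with low values. 

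Replicates were compared before averaging. Within a group the chi-square per degree of freedom of estimated counts was 12.1 to 24.0 and the Pearson correlation of log2 values across genes, which are not independent, 0.973 to 0.979, so each library differed from the others by more than sampling noise. The 2 groups share replicate numbers, which the labels do not tie to a mouse or a day.

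Before the data were examined, 38 lists of genes of pathways, T cell states and markers of other cell types were fixed, together with the tests, the alternatives and the rule for naming genes. Lists with at least 5 measured members (36) were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Members were counted as risen or fallen from the gene test, both adjusted over all genes and over the list alone. The genes named are the 10 largest rises and the 10 largest falls among genes that passed, with a mean of at least 50 in the higher group and no overlap between the groups, leaving out predicted genes and clone names. To these were added up to 4 members with the smallest p of each list that passed, in its direction, and up to 2 of each other list. Genes named outside this rule are said to be so. Some genes that the rule picks are not reported here.

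The gene test and the list test were tested on simulated data, after the real results had been computed and not before. Negative binomial counts were drawn for the 13180 tested genes from their real means and size factors, with the mean spread of genes of similar level. In the simulated comparison of itaconate against NaCl, 55.2% of 67 genes changed by 1.5-fold, 73.1% of 67 changed by 2-fold and 93.9% of 66 changed by 4-fold were called in the right direction. Of 12950 unchanged genes 7 were called, which made 4.07% of all calls. A list of 30 genes raised by 0.6 on the log2 scale was called by camera, and 0 of 20 lists of 30 unchanged genes were. The simulated genes were independent of each other, so this does not test camera on correlated genes. The simulation also changed far fewer genes than the 4741 that passed in the real data. Its recovery and its share of false calls therefore need not hold for the real comparison.

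The alternatives fixed in advance were pseudocounts of 0.1 and 10, no filter and a mean of at least 100, rescaling by median-ratio or TMM factors, quantile normalization, the replicate number as a block, each library left out, limma without the intensity trend or with robust variances, a threshold of 0.01, a minimum of a 2-fold change, an estimated inter-gene correlation, and fry. Precision weights (limma-voom) on the estimated counts and the removal of GC content and length trends were added after the data were seen. The tests of explanations were chosen after the results were seen, apart from the regrouping of libraries for the gene count, and some of their criteria were reworded after a first run. For the uneven fall of mitochondrial transcripts, 2 explanations that had been tested (a loss of all of them alike, and transcript length) were dropped to keep to 3, and are not reported. For itaconate replicate 3, 3 forms of a test were tried: the bare range of ratios between lists, bootstrap intervals of the lists with the lowest and the highest ratio, and a search over all pairs of lists. The middle form is the test reported, and the search came after it had decided nothing. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.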

Results

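CD4+ T cells, the helper lineage of T lymphocytes, were taken from the spleen of naive C57BL/6 mice and labelled with CFSE, a dye that is diluted as cells divide. They were then stimulated for 48 h with antibodies against CD3 and CD28 and 200 U of IL-2. The medium held either 5 mM itaconate, a dicarboxylate that activated macrophages make from the TCA cycle intermediate aconitate, or 5 mM NaCl as the control. The control columns of the table carry the code NAC, read here as NaCl because the labels name no other treatment. RNA was sequenced from 3 libraries per treatment, and the comparison asks how itaconate changed the transcriptome of the stimulated cells relative to NaCl. The estimated reads assigned to genes ran from 20074299 to 22755248 in the itaconate libraries and up to 24144999 in the NaCl libraries. Between 16762 and 17604 gene entries per library had a value above 0. The labels do not state that the libraries came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical.

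Most measured genes of mitosis and sterol synthesis rose with itaconate, and most of glycolysis, the hypoxia response, the ATF4 stress response and the Th2 lineage fell. These lists passed camera with a preset correlation between genes, and 0 of the 36 lists tested passed with an estimated correlation (3 at an unadjusted p under 0.05; smallest adjusted p = 0.397 with an estimated correlation). Of 38 genes of the G2 and M phases 37 rose, of 38 DNA replication genes 21 rose, and of 23 genes of glycolysis 20 fell. Genes for the mitochondrial respiratory chain encoded in the nucleus mostly did not pass the test, whereas 13 of 15 transcripts encoded by the mitochondrial genome fell. In all, 4741 of 13180 tested genes changed at a Benjamini-Hochberg adjusted p under 0.05 in limma (36.0%), 2400 of them higher and 2341 lower with itaconate, and 8439 did not pass. At least a 2-fold change was found for 587 of the higher and 738 of the lower genes. The values of the 3 itaconate libraries lay wholly above or below those of the 3 controls for 48.4% of tested genes, where chance gives 10%.

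The G2 and M phase list held 38 measured genes, of which 37 rose, 0 fell and 1 did not pass (37 and 0 adjusted over the list alone; median log2 fold change 1.06, camera adjusted p = 1.91e-13, adjusted p = 0.499 with an estimated correlation). Kif11, the kinesin motor that separates the spindle poles, rose from a normalized estimated count of 3542 ± 205 in NaCl to 8426 ± 1114 with itaconate (SD, n = 3; log2 fold change 1.24 ± 0.10 SE, adjusted p = 4.33e-06). Birc5, which encodes survivin of the chromosomal passenger complex, rose by 1.10 ± 0.11, Top2a, DNA topoisomerase II alpha, by 0.95 ± 0.10, and the spindle protein gene Tacc3 by 1.09 ± 0.11 on the log2 scale. Relative to the NaCl mean, the log2 median of the G2 and M phase list was 1.32, 1.13 and 0.64 in itaconate replicates 1, 2 and 3. In the list of G1/S and S phase genes, 21 of 38 rose and 0 fell (24 and 0 adjusted over the list alone; median log2 fold change 0.31, camera adjusted p = 3.59e-07, adjusted p = 0.410 with an estimated correlation). Among them, E2f2, an E2F transcription factor, rose by 0.90 ± 0.10, the replication checkpoint gene Clspn by 0.69 ± 0.093, the helicase subunit gene Mcm4 by 0.58 ± 0.083 and the origin licensing factor gene Cdt1 by 0.64 ± 0.091. Nucleotide synthesis genes went partly the same way, with 10 of 25 up and 2 down (12 and 2 adjusted over the list alone; median log2 fold change 0.29, camera adjusted p = 0.0301, adjusted p = 0.729 with an estimated correlation). Rrm1, the large subunit of ribonucleotide reductase, rose by 0.48 ± 0.078, Prps2 by 0.69 ± 0.10 and Paics, of purine synthesis, by 0.56 ± 0.10. The nucleotide list shares Rrm1, Rrm2 and Tyms with the G1/S and S phase list, so their agreement is partly built in. The call of the nucleotide list ended without itaconate replicate 1 (adjusted p = 0.0955), NaCl replicate 2 (0.0993) or NaCl replicate 3 (0.0632). It also ended after quantile normalization (0.0658) and in limma's rotation test fry (0.0910), within a range of 0.00941 to 0.729 over all alternatives.

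**Figure D1:**
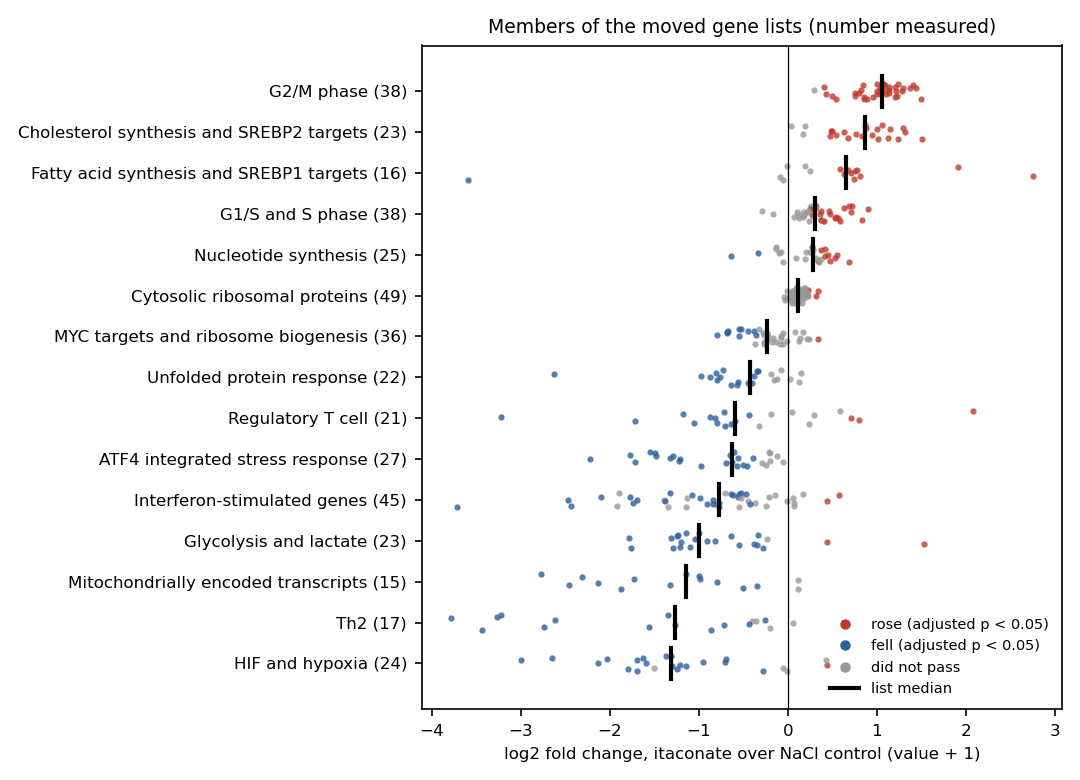
Each point is the log2 fold change of 1 measured gene, itaconate over NaCl control, on the log2(normalized estimated count + 1) scale, for the 15 gene lists that moved. Red points rose and blue points fell at an adjusted p under 0.05 in limma, grey points did not pass, and black bars are list medians, which run from −1.31 for HIF and hypoxia genes to 1.06 for G2/M genes.

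Genes induced by hypoxia-inducible factor fell together: 19 of 24 measured members fell and 1 rose (1 and 20 rose and fell adjusted over the list alone; median log2 fold change −1.31, camera adjusted p = 3.17e-09, adjusted p = 0.410 with an estimated correlation). Ero1l, an oxidoreductase gene of the endoplasmic reticulum, fell from 43778 ± 4035 to 6970.2 ± 862 (SD, n = 3), a 6.29-fold difference on the scale of the fit (log2 fold change −2.65 ± 0.10 SE, adjusted p = 3.66e-08). Higd1a changed by −1.80 ± 0.10, Fam162a by −1.70 ± 0.11 and Ndrg1 by −1.69 ± 0.11. In glycolysis and lactate metabolism, 20 of 23 genes fell and 2 rose (2 and 21 adjusted over the list alone; median log2 fold change −0.998, camera adjusted p = 1.76e-08, adjusted p = 0.410 with an estimated correlation). Ldha, the lactate dehydrogenase A gene, went from 65536 ± 758 to 28604 ± 1638 (log2 fold change −1.20 ± 0.085 SE, adjusted p = 1.74e-06). The glucose transporter gene Slc2a3 changed by −1.79 ± 0.13, hexokinase 2 (Hk2) by −1.76 ± 0.13 and Pdk1, which encodes an inhibitory kinase of pyruvate dehydrogenase, by −1.14 ± 0.085. The hypoxia and glycolysis lists share Slc2a1, Pdk1, Pfkfb3 and Pfkfb4.

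Of 27 ATF4 targets of the integrated stress response, 20 fell and 0 rose (0 and 21 rose and fell adjusted over the list alone; median log2 fold change −0.63, camera adjusted p = 1.89e-09, adjusted p = 0.410 with an estimated correlation). Trib3, a pseudokinase gene, went from 5194 ± 366 to 1545 ± 351 (log2 fold change −1.77 ± 0.13 SE, adjusted p = 2.45e-06), and the lipoprotein receptor gene Vldlr changed by −2.22 ± 0.16. Ddit3, which encodes CHOP, changed by −1.22 ± 0.094, and Ppp1r15a, which encodes the GADD34 subunit of the eIF2 alpha phosphatase, by −1.30 ± 0.10. In the unfolded protein response, 15 of 22 genes fell and 0 rose (0 and 15 adjusted over the list alone; median log2 fold change −0.43, camera adjusted p = 8.86e-06, adjusted p = 0.397 with an estimated correlation), among them the chaperone genes Hspa5 (−0.97 ± 0.079) and Hsp90b1 (−0.73 ± 0.089), the secreted factor gene Manf (−0.80 ± 0.11) and Herpud1 (−0.76 ± 0.11). Heat shock genes did not move as a list, with 4 of 15 up and 1 down (4 and 1 adjusted over the list alone; camera adjusted p = 0.143). Without itaconate replicate 3 that list passed (adjusted p = 0.0379, range over alternatives 0.0379 to 0.729). Hspa4l rose by 1.27 ± 0.14 and Hsp90aa1 changed by −0.84 ± 0.088.

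Lipid synthesis genes rose. Of 23 genes of cholesterol synthesis and other targets of SREBP2, the transcription factor that responds to low sterol, 20 rose and 0 fell (20 and 0 adjusted over the list alone; median log2 fold change 0.86, camera adjusted p = 2.80e-08, adjusted p = 0.499 with an estimated correlation). Hmgcs1, the HMG-CoA synthase gene, rose from 2020.4 ± 272 to 5821 ± 1451 (SD, n = 3; log2 fold change 1.503 ± 0.16 SE, adjusted p = 2.42e-05). The sterol demethylation genes Cyp51 and Msmo1 rose by 1.24 ± 0.12 and 1.15 ± 0.12. Of 16 fatty acid synthesis genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone; median log2 fold change 0.66, camera adjusted p = 0.00306, adjusted p = 0.499 with an estimated correlation). The stearoyl-CoA desaturase gene Scd1 rose 6.74-fold on the scale of the fit, from 340.2 ± 157 to 2308 ± 1096 (log2 fold change 2.75 ± 0.33 SE, adjusted p = 5.48e-05). The desaturase genes Fads2 (1.91 ± 0.25) and Scd2 (0.74 ± 0.10) and the fatty acid synthase gene Fasn (0.71 ± 0.10) rose less.

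**Figure D2:**
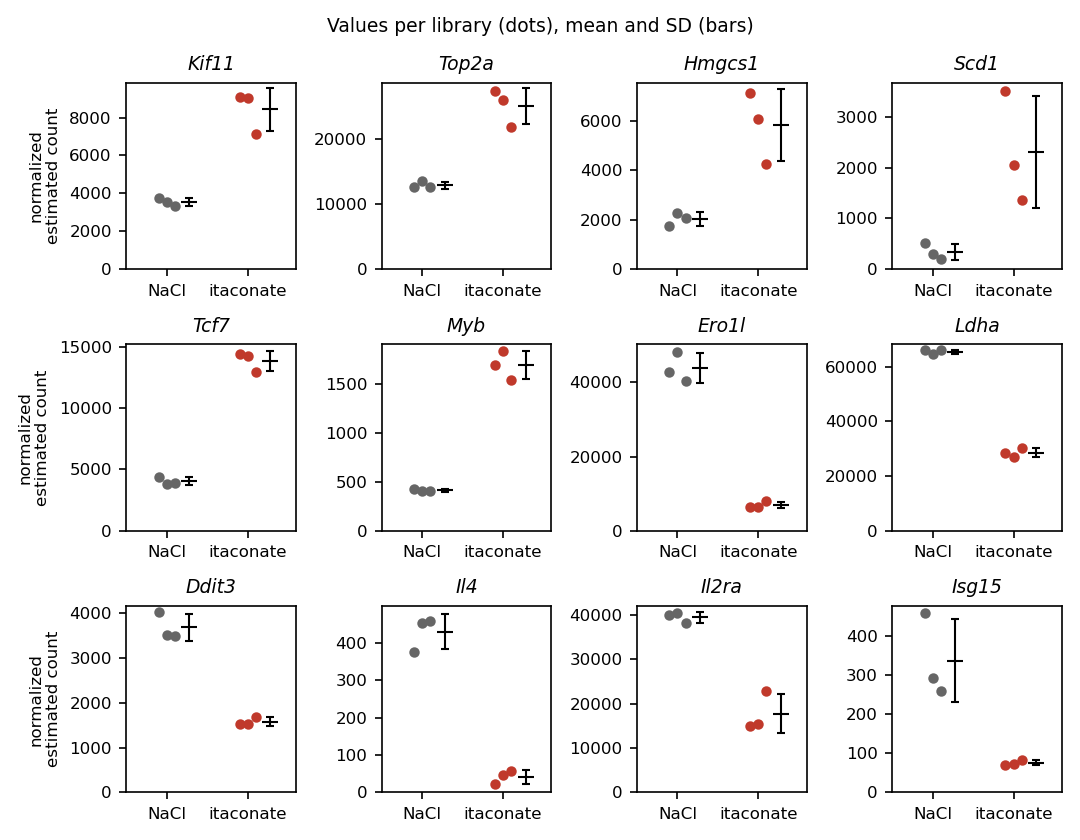
Normalized estimated counts of 12 named genes in each library (dots: grey NaCl control, red itaconate, 3 libraries each), with the group mean and SD as bars; every vertical axis starts at 0. The groups do not overlap for any of the genes drawn, as for Ldha (65536 ± 758 in NaCl, 28604 ± 1638 with itaconate) and Tcf7 (4038 ± 302 and 13840.1 ± 812).

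Of the 15 transcripts of the mitochondrial genome, 13 fell and 0 rose (0 and 13 adjusted over the list alone; median log2 fold change −1.15, camera adjusted p = 3.75e-07, adjusted p = 0.397 with an estimated correlation). All entries with a symbol starting with mt-, a wider set that leaves out nuclear copies, held 1.23%, 1.22% and 1.23% of all values in the itaconate libraries. In the controls they held 1.66%, 1.54% and 1.57%. The complex I subunit transcripts mt-Nd5 (−1.88 ± 0.091), mt-Nd4 (−2.14 ± 0.11) and mt-Nd6 (−1.73 ± 0.09) and the cytochrome b transcript mt-Cytb (−2.46 ± 0.14) had the smallest p-values of the list. mt-Cytb went from 21035 ± 1664 to 3897 ± 923 (SD, n = 3; adjusted p = 2.29e-07). The transcripts that did not pass, mt-Co1 (0.11 ± 0.10, adjusted p = 0.407) and mt-Rnr1 (0.12 ± 0.08, adjusted p = 0.281), were named after their values were seen. For 7 of the mitochondrial protein-coding genes, mt-Nd4 and mt-Co1 among them, a nuclear copy on chromosome 1 shares nearly all of its 31-base sequences with the transcript. Of 56 nuclear genes of oxidative phosphorylation, 4 rose and 6 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.776), with Uqcrq at −1.06 ± 0.10 and Uqcrh at 0.42 ± 0.091. With GC content and length trends removed, an alternative chosen after the results were seen, that list passed (median log2 fold change 0.15, adjusted p = 0.0238, range over alternatives 0.0238 to 0.977). The TCA cycle list had 4 of 22 genes up and 2 down (4 and 2 adjusted over the list alone; camera adjusted p = 0.624), and the genes that fell were the pyruvate carboxylase gene Pcx (−1.21 ± 0.15) and Suclg1 of succinyl-CoA ligase (−0.58 ± 0.088).

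**Figure D3:**
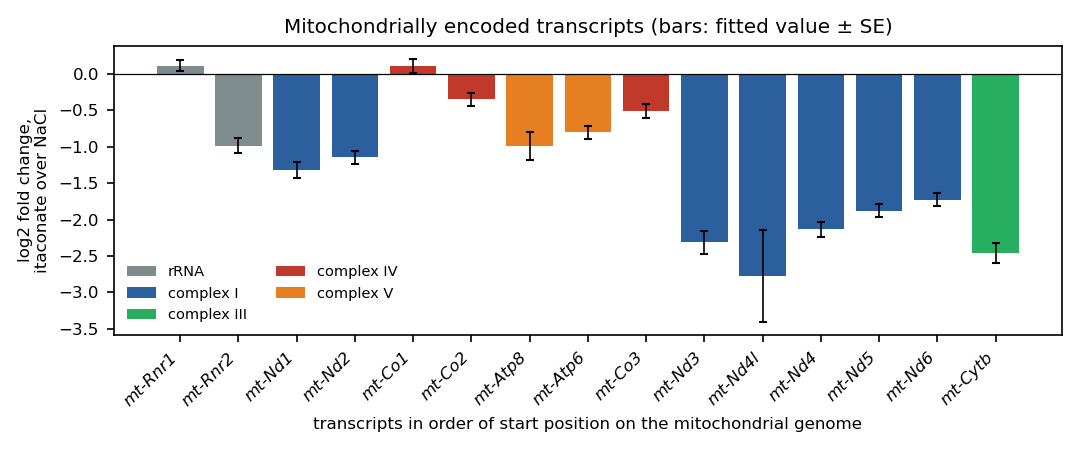
Fitted log2 fold change (bars) and its SE (error bars) of the 15 mitochondrial transcripts, itaconate over NaCl control, in order of start position on the mitochondrial genome and coloured by the complex they belong to. The change ranges from 0.12 for mt-Rnr1 and 0.11 for mt-Co1 to −2.46 for mt-Cytb and −2.77 for mt-Nd4l.

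Helper lineage genes changed unevenly. Of 17 Th2 genes, 13 fell and 0 rose (0 and 13 adjusted over the list alone; median log2 fold change −1.27, camera adjusted p = 3.47e-06, adjusted p = 0.410 with an estimated correlation). Il4, the defining Th2 cytokine gene, went from 429 ± 46.8 to 41.7 ± 18.1 (SD, n = 3), a 10.8-fold difference on the scale of the fit (log2 fold change −3.43 ± 0.31 SE, adjusted p = 7.28e-06). The Th2 master regulator gene Gata3 changed by −1.27 ± 0.12, the chemokine receptor gene Ccr4 by −1.34 ± 0.13 and Il24 by −3.79 ± 0.28. Of 21 regulatory T cell genes, 12 fell and 3 rose (3 and 13 rose and fell adjusted over the list alone; median log2 fold change −0.59, camera adjusted p = 0.0301, adjusted p = 0.499 with an estimated correlation). Il2ra, the high-affinity IL-2 receptor chain, changed by −1.18 ± 0.14, Ebi3 by −1.72 ± 0.13, Tnfrsf18 by −0.79 ± 0.086 and Tnfrsf4 by −0.70 ± 0.092. Il2ra and both TNF receptor genes are also induced by activation in other T cells. That list's call ended without itaconate replicate 1 (adjusted p = 0.0724) or NaCl replicate 2 (0.0674), and with the replicate number as a block (0.0535), in a range of 0.00938 to 0.499 over all alternatives. No other helper list passed camera. The Th1 list had 3 of 17 genes up and 7 down (camera adjusted p = 0.359; Il12rb1 −1.05 ± 0.10, Lta −1.35 ± 0.15), and the Th17 list 3 of 13 up and 5 down (adjusted p = 0.674). In the latter, the AP-1 factor gene Batf fell, with a log2 change of −1.69 ± 0.12. The follicular helper list had 5 of 14 up and 2 down (camera adjusted p = 0.624, but fry adjusted p = 0.0314, up), with the coactivator gene Pou2af1 at 1.83 ± 0.20 and the cytokine gene Il21 at −2.20 ± 0.23. Adjusted over the list alone, the counts up and down were 3 and 7 for Th1, 3 and 5 for Th17 and 5 and 2 for follicular helper genes.

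Activation and quiescence genes moved in both directions. Of 34 activation genes, 7 rose and 16 fell (8 and 17 adjusted over the list alone; median log2 fold change −0.39, camera adjusted p = 0.116). Without itaconate replicate 3 the list passed just under the threshold (median log2 fold change −0.50). The adjusted p ranged from 0.0424 to 0.729 over alternatives. Batf, an AP-1 factor gene that is also in the Th17 list, changed by −1.69 ± 0.12 (adjusted p = 1.74e-06). Myb, a transcription factor gene of progenitors, rose from 411 ± 13.4 to 1688 ± 144 (log2 fold change 2.03 ± 0.11 SE, adjusted p = 2.29e-07). Of 25 genes of naive and quiescent T cells, 12 rose and 8 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.359, but fry adjusted p = 0.0347, up). Tcf7, which encodes TCF-1 of naive and memory T cells, rose 3.43-fold on the scale of the fit, from 4038 ± 302 to 13840.1 ± 812 (log2 fold change 1.78 ± 0.087 SE, adjusted p = 1.97e-07). Inhibitory receptor and exhaustion genes had 5 of 16 up and 4 down (5 and 4 adjusted over the list alone; adjusted p = 0.876), with the transcription factor genes Tox (1.64 ± 0.19) and Nr4a1 (1.02 ± 0.10) up. Cytotoxic effector genes had 1 of 12 up and 5 down (1 and 6 adjusted over the list alone; adjusted p = 0.284), with the granule proteoglycan gene Srgn at −1.20 ± 0.12 and Serpinb9, an inhibitor of granzyme B, at −0.96 ± 0.16.

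Interferon-stimulated genes were lower with itaconate, 23 of 45 falling and 2 rising (2 and 26 rose and fell adjusted over the list alone; median log2 fold change −0.77, camera adjusted p = 5.92e-06, adjusted p = 0.499 with an estimated correlation). Isg15, a ubiquitin-like modifier gene, went from 338 ± 106 to 75.8 ± 6.66 (SD, n = 3; log2 fold change −2.10 ± 0.23 SE, adjusted p = 2.87e-05). The RNA sensor gene Dhx58 changed by −1.74 ± 0.20, the interferon regulatory factor gene Irf7 by −1.69 ± 0.23 and Ifi27l2a by −0.84 ± 0.11.

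Genes of ribosome production changed little. The list of MYC targets and ribosome biogenesis had 10 of 36 genes down and 1 up (1 and 10 rose and fell adjusted over the list alone; median log2 fold change −0.24, camera adjusted p = 0.0143, adjusted p = 0.729 with an estimated correlation). Myc itself changed by −0.55 ± 0.11, Cdk4 by −0.55 ± 0.091, Pes1 by −0.68 ± 0.10 and Imp4 by −0.80 ± 0.11. Its call ended without itaconate replicate 2 (adjusted p = 0.0810), itaconate replicate 3 (0.108) or NaCl replicate 1 (0.0828), and in fry (0.136), in a range of 1.25e-04 to 0.729 over all alternatives. The median log2 fold change of the list was −0.12 without itaconate replicate 2 and −0.16 without NaCl replicate 1. Cytosolic ribosomal protein genes had 3 of 49 up and 0 down (0 and 0 adjusted over the list alone; median log2 fold change 0.11, camera adjusted p = 0.00903, adjusted p = 0.729 with an estimated correlation). The members that passed were Rpl7a (0.34 ± 0.085), Rps2 (0.32 ± 0.11) and Rps25 (0.22 ± 0.082), while Rps12 was at 0.22 ± 0.085 (adjusted p = 0.0600, range over alternatives 0.00338 to 0.191). Rps12 passed with the replicate number as a block (0.0302), means of at least 100 (0.0424) and robust variances (0.0380). It also passed with voom (0.0349) and with GC content and length trends removed (0.00338), both chosen after the results were seen. That list's call ended without itaconate replicate 2 (adjusted p = 0.0810), NaCl replicate 1 (0.0770) or NaCl replicate 2 (0.0674), and in fry (0.158), in a range of 1.48e-07 to 0.729 over all alternatives. Over the alternatives the median of the ribosomal protein list ran from 0.088 to 0.27. The log2 fold change ran from 0.29 to 0.54 for Rpl7a and from 0.19 to 0.41 for Rps25. The adjusted p of Rps2 ranged from 0.00606 to 0.138 and that of Rps25 from 0.00127 to 0.171 over the alternatives. Each lost its call when any of several single libraries was left out. For Rps2 these were itaconate replicate 1 (0.133) or 2 (0.111) and NaCl replicate 2 (0.138) or 3 (0.0983). For Rps25 these were itaconate replicate 1 (0.107) or 2 (0.171) and NaCl replicate 1 (0.122), 2 (0.108) or 3 (0.0623). Rps2 and Rps25 also lost their calls with no filter on low values (0.109 and 0.126) and without the intensity trend (0.107 and 0.104), and Rps25 with a pseudocount of 10 (0.0531).

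Other metabolic and stress lists did not pass camera. Of these, fry called itaconate handling (down, adjusted p = 0.0108), mTORC1 (down, 0.0191), NRF2 targets (down, 0.0347) and fatty acid oxidation (up, 0.0347). With GC content and length trends removed, an alternative chosen after the results were seen, camera called mTORC1 as well (adjusted p = 0.0420, range over alternatives 0.0191 to 0.720). Of 19 NRF2 antioxidant targets, 2 rose and 6 fell (camera adjusted p = 0.130), with the heme oxygenase gene Hmox1 at −1.32 ± 0.17 and the exporter gene Abcc1 at −0.79 ± 0.092. Serine, glycine and one-carbon genes had 1 of 21 up and 3 down (adjusted p = 0.674), the last including the mitochondrial folate enzyme genes Mthfd1l (−0.90 ± 0.10) and Aldh1l2 (−0.92 ± 0.11). Aspartate and glutamine genes had 1 of 17 up and 4 down (adjusted p = 0.630), with the argininosuccinate synthase gene Ass1 at 0.81 ± 0.088 and the aspartate aminotransferase gene Got1 at −1.09 ± 0.11. The amino acid transport and mTORC1 list had 1 of 14 up and 5 down (adjusted p = 0.130), with Slc7a5, the large neutral amino acid transporter gene, at −0.97 ± 0.11 and Eif4ebp1 at −1.16 ± 0.12. Fatty acid oxidation genes had 5 of 19 up and 3 down (adjusted p = 0.776), and Cpt1a, which controls fatty acid entry into mitochondria, rose by 1.23 ± 0.10 and Acadl by 0.45 ± 0.089. Of 11 genes that handle itaconate or succinate, 1 rose and 3 fell (adjusted p = 0.627). Slc13a3, a dicarboxylate importer gene, went from 284 ± 10.3 to 43.1 ± 8.59 (log2 fold change −2.71 ± 0.23 SE, adjusted p = 4.48e-06), and Clybl, of citramalyl-CoA breakdown, changed by −1.03 ± 0.14. p53 targets had 10 of 22 up and 4 down (adjusted p = 0.244; Sesn1 1.34 ± 0.12, Sesn2 −1.33 ± 0.12), and apoptosis regulators 5 of 24 up and 5 down (adjusted p = 0.624). Of the latter, the pro-apoptotic gene Bcl2l11 rose by 1.33 ± 0.12 and the anti-apoptotic gene Bcl2l1 changed by −0.83 ± 0.083. Adjusted over the list alone, the counts up and down were 2 and 6 for NRF2, 1 and 3 for serine, 1 and 4 for aspartate, 1 and 5 for mTORC1, 5 and 3 for fatty acid oxidation, 1 and 3 for itaconate handling, 10 and 5 for p53 and 5 and 5 for apoptosis.

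Markers of other cell types showed no common direction. Genes of the CD8 T lineage had 1 of 8 up and 0 down (camera adjusted p = 0.781), with the protease gene Ctsw at 1.08 ± 0.16 and Cd8b1 at −0.23 ± 0.14 (adjusted p = 0.235), that is 293 ± 25.6 with itaconate and 344 ± 22.9 with NaCl. B cell markers had 3 of 16 up and 2 down (adjusted p = 0.674), with the immunoglobulin heavy chain gene Ighm at 0.70 ± 0.10 and the MHC class II gene H2-Ab1 at −1.89 ± 0.15. Myeloid and dendritic markers had 4 of 10 up and 0 down (adjusted p = 0.624), with Itgam rising from 14.3 ± 9.12 to 59.0 ± 17.2 and the cathepsin gene Ctss from 799 ± 14.1 to 1077 ± 95.4. Adjusted over the list alone, the counts up and down were 1 and 0 for CD8, 3 and 2 for B cell and 4 and 1 for myeloid markers. NK cell and erythroid or platelet markers had 2 measured genes each and were not tested as lists. Itga2 changed by −1.52 ± 0.25 and Eomes, also a T cell gene, by 0.95 ± 0.19, Car2 rose by 2.30 ± 0.47, and Itga2b was at 0.026 ± 0.33 (adjusted p = 0.959).

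Single genes were ranked among those with a mean of at least 50 in the higher group and no overlap, leaving out predicted genes. With the pseudocount of 1, the largest rise was that of Npas4, an activity-dependent transcription factor gene, from 10.2 ± 5.34 to 186 ± 121 (15.7-fold on the scale of the fit; log2 fold change 3.97 ± 0.48 SE, adjusted p = 6.02e-05). Then came the RAS association domain gene Rassf4 (3.59 ± 0.52), the type I receptor gene Acvr1c of the TGF-beta family (3.33 ± 0.55), the syntrophin gene Sntb1 (3.30 ± 0.20), the chitinase gene Chit1 (2.88 ± 0.61), Serpinb5 (2.84 ± 0.35), Rhbdl1 (2.78 ± 0.67), Scd1, Plekhg4 (2.74 ± 0.43) and the acyl-CoA thioesterase gene Acot1 (2.66 ± 0.57). With a pseudocount of 10 the log2 fold change of Rassf4 was 2.23, below Sntb1 (3.04), Scd1 (2.72), Acvr1c (2.44) and Serpinb5 (2.30), so the order of the rises depends on the pseudocount. The call of Rhbdl1 ended in limma without the intensity trend (adjusted p = 0.0582, range over alternatives 0.00138 to 0.0582), and its log2 fold change was 1.78 without NaCl replicate 2. The largest fall, with that pseudocount, was that of the adaptor gene Sh3d19, from 86.6 ± 5.14 to 2.77 ± 3.32 (log2 fold change −4.98 ± 0.69 SE, adjusted p = 1.58e-04). With a pseudocount of 10 the log2 fold change of Sh3d19 was −2.95 and that of Il24 −3.66, so the rank depends on the pseudocount. Other large falls were those of the adaptor gene Bcar1 (−4.46 ± 0.55), Proser2 (−4.15 ± 0.73), the glycogen phosphatase gene Epm2a (−3.89 ± 0.46), Il24, the interferon-induced gene Ifi44 (−3.72 ± 0.61), the long noncoding RNA gene Trp53cor1 (−3.67 ± 0.31) and the ephrin gene Efna5 (−3.56 ± 0.46). With a pseudocount of 10, Bcar1 was at −2.89, Proser2 at −2.42 and Ifi44 at −2.29. Among these, Sntb1 had 395 ± 34.5 against 39.2 ± 3.10 and Il24 101 ± 48.2 against 1337 ± 328, with itaconate and NaCl respectively.

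In the GRCm38 assembly, which is mm10, GENCODE release 21 places Npas4 on chromosome 19: 4984355 to 4990316, minus strand, and Sntb1 on chromosome 15: 55636388 to 55906949, minus strand. Scd1 lies on chromosome 19: 44394455 to 44407879, minus strand, and Kif11 on chromosome 19: 37376403 to 37421859, plus strand. Tcf7 lies on chromosome 11: 52252371 to 52283014, minus strand, and Il4 on chromosome 11: 53602982 to 53618669, minus strand. Ero1l lies on chromosome 14: 45283087 to 45318771, minus strand, and Ldha on chromosome 7: 46841475 to 46855627, plus strand. Sh3d19 lies on chromosome 3: 85971109 to 86130526, plus strand, and Hmgcs1 on chromosome 13: 119690379 to 119708260, plus strand. All 10 are protein-coding genes. Exon bases are shared with a neighbouring gene for 81.4% of Rhbdl1, 68.7% of Itgam, 44.1% of Trp53cor1, 27.2% of Tnfrsf18, 24.8% of Rps25, 23.4% of Ebi3 and 22.5% of Higd1a, whose reads cannot be told apart there by position alone. The symbol Ddit3 stands on 2 entries of the table, of which the other had a value of 0 in every library.

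Over the 36 lists tested, 15 passed camera with its preset correlation, 6 up and 9 down. With a correlation estimated from the libraries, 0 passed camera (3 had an unadjusted p under 0.05), the smallest adjusted p being 0.397 for the mitochondrial and unfolded protein response lists. In fry, which asks whether a list's genes move in a common direction without comparing them with other genes, 18 lists passed, 12 of the 15 among them. Regroupings of the 6 libraries that mixed the treatments moved 5 to 15 lists each with the preset correlation, the highest as many as the real grouping. That regrouping called 0 genes in limma (114 at an unadjusted p under 0.05). Its groups held unequal numbers of itaconate and NaCl libraries, so it kept part of the treatment difference and placed the rest within the groups. It therefore does not show how many lists would move without a treatment effect. The median, mean and camera direction of a list differed in sign for 7 lists that did not pass. These were aspartate (median 0.012, mean −0.14, down), nuclear oxidative phosphorylation (0.038, −0.0043, up), fatty acid oxidation (−0.013, 0.082, up), itaconate handling (0.032, −0.31, down), inhibitory receptors (−0.23, 0.081, down), CD8 lineage (−0.0058, 0.14, up) and myeloid markers (−0.12, 0.072, up). Itaconate replicate 3 lay nearer to the controls than the other itaconate libraries on the first principal component, with a score of −29.4 against −51.6 and −47.5, the controls lying between 41.5 and 45.3. Without that library, 4998 genes changed.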

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

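The weighted fit of estimated counts (voom) and the removal of GC content and length trends were chosen after the results were seen; the other alternatives were planned. Genes changed numbered 2991 at an adjusted p under 0.01 (1520 higher, 1471 lower) and 1325 with at least a 2-fold change (587 higher, 738 lower), as stricter thresholds must give. Leaving out each library in turn gave 3478 (without itaconate replicate 2) to 4998 (without itaconate replicate 3) changed genes, 1730 to 2459 higher and 1748 to 2539 lower, with fewer samples in each fit, and 12 to 16 lists moved. Every other alternative for the gene count, within 3651 (limma without the intensity trend) to 5636, stayed within 1.5 times the 4741 reported. Rescaling by median-ratio factors changed no value, since the table already has that scaling, and no scaling moved the median of all genes by over 0.1. Lists moved fell to 0 in camera with an estimated correlation (3 at an unadjusted p under 0.05) against 15 with the preset correlation and 18 in fry. Camera with an estimated correlation also uses fewer degrees of freedom, so the drop cannot be credited to the correlation between genes alone. The planned whole-read count tests (edgeR, DESeq2) were not run, because whole reads could not be recovered.

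Over all list results, 596 kept their direction and side of the threshold, 31 lost their call, 11 gained it and 8 changed sign; for named genes the numbers were 2151, 16, 5 and 5. Each result that changed sign had not passed. The inhibitory receptor list had a median of −0.23 with means of at least 100, −0.13 without itaconate replicate 2, −0.23 in fry and −0.22 with voom, where the direction of the test turned. Its leave-one-out medians ran from −0.32 to −0.13. Nuclear oxidative phosphorylation had 0.013 after quantile normalization, 0.010 without itaconate replicate 1 and −0.010 without NaCl replicate 2 (leave-one-out range −0.010 to 0.080). The CD8 list had 0.061 without NaCl replicate 3 (range −0.050 to 0.20). Itga2b was at −0.08, −0.14 and −0.29 without itaconate replicate 2, itaconate replicate 3 and NaCl replicate 1 (range −0.29 to 0.30), −0.0022 with voom and −0.048 with GC and length trends removed. Rhbdl1 and Impdh2 lost their calls without the intensity trend (adjusted p = 0.0582 and 0.0509). The cause was not tested.

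With the replicate number as a block, 5636 genes changed (2855 higher, 2781 lower) and 14 lists moved, the regulatory T cell list having an adjusted p of 0.0535. Deviations from the group means correlated at 0.146, 0.0383 and 0.128 across genes between libraries of the same number. Each library correlated best with its own number, and the block raised the number of changed genes, both hints of pairing. The labels do not tie the numbers to a mouse or a day, so the main fit had no block. Whether the samples are paired stays open. In the simulated comparison 55.2% of 1.5-fold changes were recovered, a share that need not hold for the real one, where far more genes changed. Whether depth or the spread between libraries limits the recovery was not tested.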

Other observations

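The gene families, and all tests of explanations apart from the regrouping of libraries for the gene count, were chosen only after the results were seen. Of 25 gene families picked by their symbols, 6 passed camera with the preset correlation and 0 with an estimated correlation. Some of these share members with the lists reported above and are not independent of them. For example, the kinesin genes Kif11, Kif20a, Kif23 and Kif2c are also in the G2/M list. The interleukin genes Il4, Il5, Il13 and Il24 are in the Th2 list, and the proteasome genes Psmb8 and Psmb9 in the interferon list. The ATF4 list holds synthetase genes such as Nars and Wars. Of 15 interleukin genes, 10 fell and 0 rose (median log2 fold change −1.89, camera adjusted p = 7.29e-04, adjusted p = 0.592 with an estimated correlation). Outside the lists above, Il23a changed by −3.34 ± 0.25 and Il6 by −1.89 ± 0.55 (SE), and of the Th2 cytokines, Il13 changed by −3.27 ± 0.33 and Il5 by −2.61 ± 0.51. Il2 (−0.98 ± 0.40, adjusted p = 0.0722) and Il17a (0.90 ± 0.46, adjusted p = 0.144) did not pass. Of 18 cytosolic aminoacyl-tRNA synthetase genes, 10 fell and 1 rose (median −0.41, camera adjusted p = 0.00601, adjusted p = 0.719 with an estimated correlation), with Dars at −1.07 ± 0.084 and Qars, the riser, at 0.38 ± 0.082.

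Of 27 kinesin genes, 16 rose and 2 fell (median 0.76, camera adjusted p = 4.17e-04, adjusted p = 0.719 with an estimated correlation). The mitotic kinesin genes Kif20a (1.37 ± 0.17) and Kif18b (1.16 ± 0.11) rose, and the transport kinesin genes Kif3a (−0.64 ± 0.13) and Kif3b (−0.50 ± 0.085) fell. Condensin and cohesin genes had 9 of 15 up and 0 down (camera adjusted p = 0.00213, adjusted p = 0.719 with an estimated correlation), Ncaph rising by 0.89 ± 0.10. Proteasome subunit genes had 13 of 46 down and 1 up, and GIMAP GTPase genes 5 of 9 down and 0 up (camera adjusted p = 0.0181 each, adjusted p = 0.719 each with an estimated correlation).

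The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split changed 4741 genes and the highest of the others 0, so 1 split reached that count. The real split moved 15 lists and the others 5 to 15 each, so 2 splits reached that count. Each of the other splits kept part of the treatment difference and left the rest within its groups, so their counts are not those of libraries without a treatment effect. The median change of 13 of the 15 moved lists was larger in size under the real split than under any other. The exceptions were the MYC and ribosomal protein lists, and for 5 lists the median was over 2 times as large. These lists were chosen because they passed under the real split, so larger medians there were favoured in advance and are no support.

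Cell-cycle genes rose while HIF and glycolysis genes fell. Removing GC content and length trends from each library left at least 0.964 of the median change of the G2/M, HIF and glycolysis lists, and all 3 passed camera with the preset correlation, which argues against such a bias as the whole cause; without that removal the lists have adjusted p = 0.499, 0.410 and 0.410 with an estimated correlation. T cells diluted by other cells would have lost their lineage genes by about as much as the HIF list fell. The 16 T cell lineage genes had a median change of −0.072 (bootstrap interval −0.20 to 0.21, 4 rose and 4 fell), which argues against such dilution as the whole cause. The interval resamples these genes and not the libraries, and a smaller dilution was not excluded. An effect of itaconate on glycolytic and hypoxia-response transcription may account for the fall of the HIF and glycolysis genes, as a hypothesis. A difference in the timing or number of divisions at 48 h stays open. Cells sorted by equal CFSE dilution would match the number of divisions but not their timing. RNA of such cells was not analysed here.

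Mitochondrial transcripts fell unevenly. Summing each with its nuclear copy on chromosome 1 left the SD of the 15 changes at 0.966 of its value, against a division of reads with those copies as the cause. The mean change was −1.97 for the 8 protein-coding genes of complexes I and III and −0.51 for the 5 of complexes IV and V (exact permutation p = 0.00155, two-sided, over 1287 regroupings). mt-Nd4l overlaps mt-Nd4 in position and mt-Atp8 overlaps mt-Atp6, yet the permutation counted each as its own unit, so its p may be too small. The change also grew with distance along the heavy strand (Spearman's rho −0.68 over 14 transcripts, permutation p = 0.00881, two-sided, and −0.60 without mt-Rnr1). Both the grouping by complex and the correlation with position were chosen after the values were seen. Their small p-values may have been favoured in advance and are no support. mt-Nd6, which is transcribed from the other strand and was left out of that correlation, changed by −1.73, and mt-Nd1 (−1.32 ± 0.11) and mt-Nd2 (−1.15 ± 0.095) fell more than mt-Co1 (0.11 ± 0.10) and mt-Co2 (−0.35 ± 0.09), which lie further along the heavy strand; progressive loss along that transcript would give neither, although these transcripts were picked after their values were seen and the strand setting of the libraries is not given in the sources used here. Transcripts are not independent replicates, and the complexes differ in position. Such loss, which may account for part of the pattern only, and a difference in stability between the mRNAs of the complexes both stay open. Itaconate is the treatment compared, and whether it acts through either was not tested.

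Itaconate replicate 3 lay nearer to the controls. Among genes at least 4-fold apart in the other itaconate libraries, with a mean of at least 200, its risen genes (20) were displaced by a median of 40.7% of the way to the controls and its fallen genes (75) by 8.68%. The difference of 32.0 percentage points argues against control RNA mixed into that library as the whole cause, which would displace both alike. The interquartile ranges, 14.0% to 57.9% for risen and 2.47% to 16.8% for fallen genes, overlap in part. In itaconate replicate 2 the medians were 9.46% for risen and −0.74% for fallen genes. A smaller share of control RNA in replicate 3 was not excluded. A response smaller by the same share in every list stays open: over the 10 moved lists with a median change over 0.5 on the log2 scale, the ratio of its change to that of the other itaconate libraries ran from 0.369 (regulatory T cell) to 0.990 (ATF4; MYC, at 1.53, and the unfolded protein response, at 1.07, are below that size), but the 95% bootstrap intervals of these overlap, the lower bound of the highest lying at −0.24 from the upper bound of the lowest. That was the middle of 3 forms tried, and a later search over 45 pairs of lists found ATF4 and G2/M apart by 0.0707 at 99%, which is not counted here because the pair was picked by the search.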
